A study of Mus musculus with 6 samples.

How the data were processed

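The series holds 6 chromatin immunoprecipitation sequencing (ChIP-seq) libraries made from mouse retina with a rabbit antibody against BMAL1, the clock transcription factor that the Bmal1 gene (listed as Arntl in the gene table used here) encodes. ChIP-seq recovers DNA that was bound by the antibody's target and sequences it, so that bound places appear as peaks of reads. Per the labels, 3 libraries came from wild-type mice (control 1 to 3) and 3 from mice with a conditional knockout of Bmal1 (Bmal1 CKO 1 to 3), all of the C57BL/6 strain. The labels do not say in which retinal cells the gene was deleted, how old the mice were or at which time of day the retinas were taken. They say only that pups were weaned at postnatal day 20.

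The deposited data are 1 peak list per library. The numbers in the names of the deposited lists differ from the replicate numbers in the sample titles, and lists were assigned to libraries by the series record alone. The submitters' processing notes name Trim Galore, Bowtie2, MACS2 and the mouse genome build mm10. Versions, parameters and the use of an input library are not given in the sources used here. For each peak the authors deposited a fold enrichment at the summit over the local background of that library (a ratio), the −log10 p-value and −log10 q-value at the summit, a whole-number score that equals 10 times the −log10 q-value rounded down, and the summit position. The lowest deposited −log10 q-value of each list lay between 1.30 and 2.53. Peaks were called per library, so replicates can be compared by overlap. The fold and q-value of a peak are the authors' own values and are relative to its own library. They were used here to describe, rank and filter peaks within a list, and no difference in fold between libraries was tested.

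The peak lists carry no read totals, so depth was recovered from the deposited fold and p-values. With a pseudocount of 1 in the fold and a Poisson p-value, each pair of values can be solved for the number of fragments stacked at the summit and the expected background there. This was done for every peak of the 4 shorter lists and for 3000 randomly drawn peaks of each of the 2 longest. The stacked number came out whole, within 0.02, for 100.0% of peaks in every library. On 1000 simulated pairs the method returned the true numbers in 100.0% of cases. The background had one lowest, repeated value per library, taken here as the level across the genome, and otherwise moved in steps of 0.02 in at least 99.5% of peaks per library, which is what 200 bp fragments counted over 10 kb give. If this reading of the values holds, the genome-wide level is proportional to the number of fragments the peak caller used, and it serves here as the measure of relative depth. It was 3.46 fragments per base in control 1, 0.609 in control 2, 0.852 in control 3, 2.78 in Bmal1 CKO 1, 5.83 in Bmal1 CKO 2 and 0.560 in Bmal1 CKO 3. Depth therefore differed by 10.4 times between the deepest and the shallowest library. The unscaled steps of 0.02 would also follow if each background was counted in the library itself, with no input. The sources used here do not say whether an input was used.

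Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose chromosome coordinates are those of mm10. The table has no strand, so transcription start sites could not be told from the other end of a gene. A peak was called at a gene end when its summit lay within 1 kb of either annotated end of one of 21900 protein-coding genes. This replaced the planned window around start sites. Of a gene's pair of ends 1 is the promoter end, and neighbouring genes can share a peak. All members of the 12 gene lists were found in the table. No genome sequence was used here, so the planned count of the E-box CACGTG, the motif bound by CLOCK and BMAL1, was not made.

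The gene lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The window around both gene ends, the gene body window, the alternatives without the 2 longest lists, the gene families, the dense intervals, the common p-value limit and the depth calculation were chosen afterwards. The text names members of the core clock, thyroid hormone and cone lists that have peaks, up to 10 regions called in controls and no CKO library (all 3 controls, or 2 of them where fewer than 3 such regions exist), the mirror set, up to 10 regions called in all libraries in order of their lowest fold, and the 5 peaks of each list with the highest −log10 q-value. The top 5 peaks per list, which share most members, are partly given as a summary. The values of some single genes of the lists are not reported here.

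Numbers of peaks (log10), shares of peaks at gene ends and shares of list genes with a peak were compared between genotypes with an exact two-sided permutation test over the 20 assignments of 6 libraries to 2 groups of 3. The smallest p this design allows is 0.10, so no such comparison can reach 0.05. Nothing in the labels says more than that 3 mice per genotype were compared, and the spread is that between these libraries. Overlap between lists was the share of the shorter list's peaks that share at least 1 bp with a peak of the longer list, set against circular shifts of the shorter list along each chromosome. Peaks of all libraries that overlapped by at least 1 bp were merged into regions. Within each library, Fisher's exact test (one-sided) compared each gene list with all other protein-coding genes, with Benjamini-Hochberg adjustment over 72 tests. Genes are not replicates, so these tests describe a library. Confidence intervals are exact Clopper-Pearson intervals at 95% and cover counting error only.

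The code was tested on simulated lists. It found 100.0% of regions planted in 1 genotype or in all libraries and 100.0% of 200 genes given a peak at an end. Against the gene-end peaks of control 1 over 21900 genes, a simulated list of 20 genes of which 95% had a peak was called at an unadjusted p under 0.05 in 95.0% of 200 draws, and a list with 85% in 41.0%. For Bmal1 CKO 2 these shares were 99.0% and 83.0%. Alternatives were stricter q-value and fold limits, the same number of peaks per library, other chromosomes, a wider window, a larger overlap, a replicate block and each library left out in turn. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.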

Results

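BMAL1 ChIP-seq was carried out on retinas of 3 wild-type mice and 3 mice with a conditional knockout (CKO) of Bmal1. The study's title ties the gene to thyroid hormone, to the spectral identity of cones (which opsin a cone makes) and to cone function. The peak lists address where BMAL1 antibody signal lies in retinal chromatin and whether it differs when the gene is deleted. A list held 179475 peaks in control 1, 410 in control 2 and 372 in control 3, and 1444 in Bmal1 CKO 1, 138254 in Bmal1 CKO 2 and 519 in Bmal1 CKO 3. Lists were assigned to libraries by the series record, which the lists themselves cannot check. The lists covered 58.8 Mb, 0.147 Mb and 0.140 Mb in the controls and 0.479 Mb, 43.4 Mb and 0.180 Mb in the CKO libraries. The 2 long lists, control 1 and Bmal1 CKO 2, thus belonged to different genotypes, and the shorter of them was 95.7 times as long as the longest of the other 4. The recovered background was 3.46 and 5.83 fragments per base in these 2 libraries, 2.78 in Bmal1 CKO 1, and 0.560 to 0.852 in the remaining 3.

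**Figure D1:**
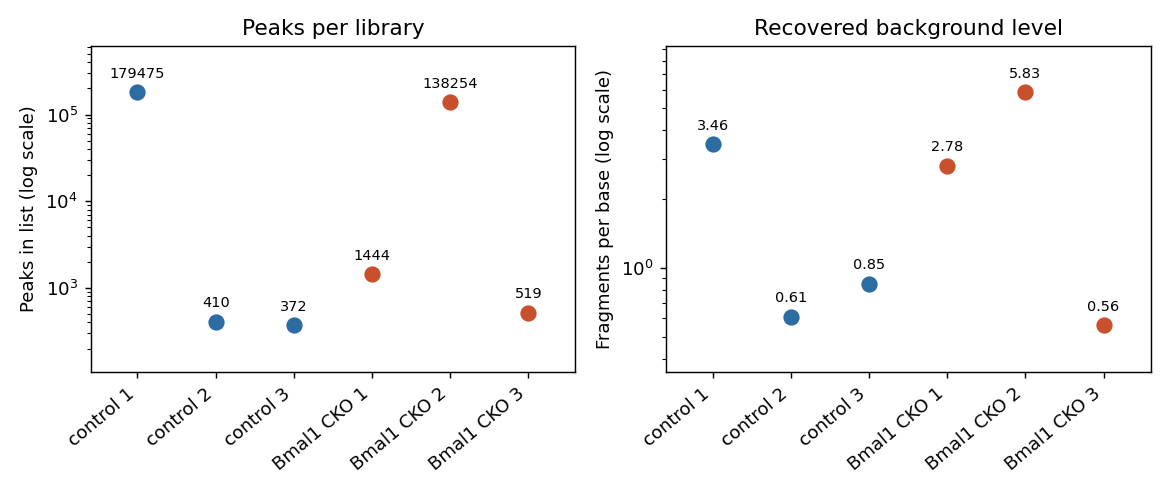
Left, number of peaks in each library's list; right, background level in fragments per base, recovered from the deposited fold and p-values; both axes are logarithmic, blue marks control and orange Bmal1 CKO libraries. Control 1 (179475 peaks) and Bmal1 CKO 2 (138254 peaks) stand apart from the other 4, while Bmal1 CKO 1 has 1444 peaks at a background of 2.78 against 3.46 in control 1.

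The targeted gene is given first. The peak lists do not measure whether Bmal1 was lost, and a peak at the locus cannot check the labels. Arntl (Bmal1; mm10 chromosome 7, 113178471 to 113314126) had no peak within 1 kb of either gene end in any library. Within the gene and 10 kb around it control 1 listed 19 peaks and Bmal1 CKO 2 listed 15, with a highest fold enrichment of 5.39 and 3.66. The other 4 libraries listed none there. In their lists 0.759% to 2.05% of the protein-coding genes outside the clock list had a peak in the gene or within 10 kb.

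The number of peaks did not separate the genotypes. The mean was 60086 ± 103394 peaks (SD, n = 3) in controls and 46739 ± 79256 (SD, n = 3) in CKO libraries, so the spread within a genotype exceeded the mean. On the log10 scale the CKO mean was 0.193 higher (3.67 ± 1.29 against 3.48 ± 1.54, SD, n = 3 each), with an exact permutation p of 0.70 (two-sided; smallest possible 0.10). Without the 2 long lists the difference was 0.346, with an exact permutation p of 0.333, the smallest that 2 libraries against 2 allow. The direction turned without control 2, without control 3 and without Bmal1 CKO 2 (−0.240, −0.262 and −0.542).

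In the long lists most protein-coding genes had a peak at a gene end, among them 14 of 20 genes that retina keeps silent in control 1 and 6 of 20 in Bmal1 CKO 2. Control 1 had a summit within 1 kb of an end of 15226 of 21900 protein-coding genes (69.5%), Bmal1 CKO 2 of 12898 (58.9%), and 11974 genes had one in both. Of single peaks, 10.5% in control 1 and 11.2% in Bmal1 CKO 2 lay at a gene end, where uniform placement gives 3.12% and 3.08%. The short lists had 2.93% in control 2, 3.76% in control 3, 5.26% in Bmal1 CKO 1 and 4.43% in Bmal1 CKO 3, against 3.03% to 3.30% from uniform placement. Between genotypes the share was 5.72% ± 4.14 in controls and 6.97% ± 3.70 in CKO libraries (SD, n = 3 each; exact permutation p = 0.50), a difference smaller than the spread between replicates. That difference of 1.25 percentage points turned to −0.151 without control 2 and to −0.875 without Bmal1 CKO 2, and reached 3.62 without control 1. Without the 2 long lists both CKO libraries (5.26% and 4.43%) lay above both controls (2.93% and 3.76%), with an exact permutation p of 0.333, the smallest that 2 libraries against 2 allow.

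Genes of the circadian clock carried peaks in the long lists of both genotypes and none at their ends in the 4 short lists. In the short lists 0.0594% to 0.343% of the other protein-coding genes had an end peak, so the absence is not particular to clock genes. Scaled to the background of control 2, control 3 and Bmal1 CKO 3, 0 of the 19 clock genes with an end peak in control 1 had a −log10 p-value as high as the lowest in those lists, which was 5.05 to 6.76 against 2.76 in control 1 and so depends on the lists as well as on depth. Scaled to Bmal1 CKO 1, 16 of the 19 from control 1 and 6 of the 15 from Bmal1 CKO 2 did, and its list held no clock gene end peak. That list had an end peak at only 0.343% of the other protein-coding genes. Of 22 core clock and clock output genes, 19 (86.4%) had a peak at a gene end in control 1 and 15 (68.2%) in Bmal1 CKO 2. Among them 13 had one in both libraries, 6 only in the control 1 list, 2 only in the Bmal1 CKO 2 list, and Arntl in neither. Over all protein-coding genes the control 1 list also had more (15226 against 12898, with 11974 in both). An excess in control 1 is thus not particular to clock genes. All 22 had a peak somewhere in the gene or within 10 kb in both libraries, as had 92.5% and 87.8% of all other protein-coding genes (Fisher's exact test, one-sided, p = 0.182 and 0.0576, adjusted p = 1 for both). The list did not pass the test against all other genes (Fisher's exact test, one-sided, p = 0.0621 in control 1 and 0.255 in Bmal1 CKO 2, adjusted p = 1 for both). In control 1, simulated lists of 20 genes with a share of 85% were missed in most draws even before adjustment. The result in control 1 therefore does not exclude enrichment of clock genes.

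Among the period genes, which encode repressors of CLOCK and BMAL1, Per2 (chromosome 1, 91415977 to 91459351) had a summit at 91459470 in control 1, with a fold enrichment of 2.88, and at 91459320 in Bmal1 CKO 2, with 2.42. Per3 (chromosome 4, 150997018 to 151044707) had summits 121 bp and 110 bp outside its upper end, with folds of 5.05 and 3.27. Per1 (chromosome 11, 69095108 to 69109965) had a summit 198 bp outside its lower end in control 1, with a fold of 2.06, and none at an end in Bmal1 CKO 2. The cryptochromes, the partners of the period proteins, had peaks in both libraries, with folds of 4.63 and 4.40 at Cry1 and 3.63 and 2.46 at Cry2. Nr1d1, which encodes the repressor REV-ERB alpha (chromosome 11, 98767932 to 98775377), had a fold of 2.54 at 19 bp inside its upper end in control 1 and no end peak in Bmal1 CKO 2, whereas Nr1d2 had 4.42 and 3.10. Ciart, a repressor of CLOCK and BMAL1, had 3.93 and 3.23, and Usp2, a ubiquitin protease with clock-controlled expression, had 3.53 and 3.20. The output factor Tef had 3.29 and 2.35 at the same summit, 81802603 on chromosome 15, and its relative Hlf had 3.49 and 2.77. Dbp, another factor of that family, had an end peak only in the Bmal1 CKO 2 list, with a fold of 2.03, and Clock likewise, with 3.37. Npas2 had 3.65 and 2.54, Bhlhe41 had 3.02 and 2.59, Rorb had 4.18 and 3.59, and the kinase gene Wee1 had 3.70 and 3.41 in control 1 and Bmal1 CKO 2. Nfil3, Bhlhe40 and Rora had an end peak only in the control 1 list, with folds of 3.07, 2.69 and 3.16. Over all end peaks the median fold was 3.59 in control 1 and 2.95 in Bmal1 CKO 2. The highest end folds of the clock genes had medians of 3.49 and 3.10. Those of 20 genes used in nearly all cells had medians of 3.84 and 3.15. Lower folds in Bmal1 CKO 2 were thus not particular to clock genes.

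**Figure D2:**
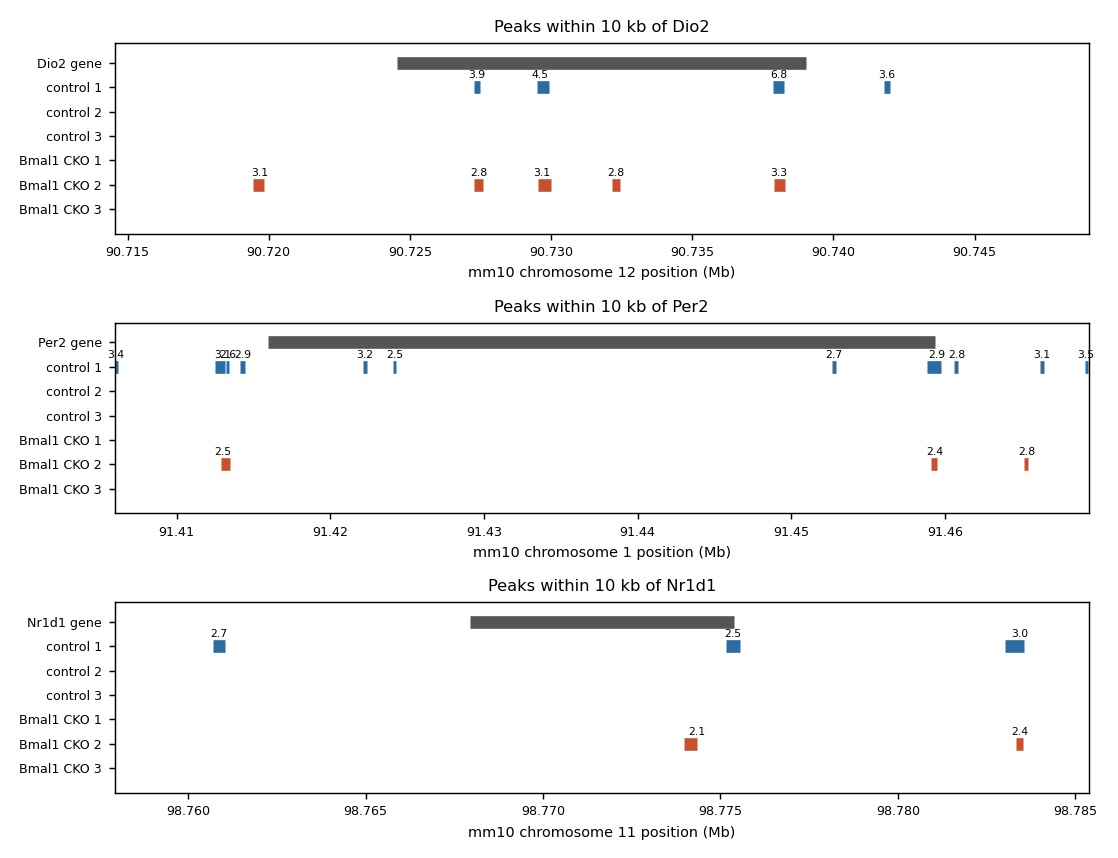
Peaks in the 6 libraries (blue control, orange Bmal1 CKO) over the genes Dio2, Per2 and Nr1d1 (grey bars) and 10 kb to either side, by mm10 position in Mb; the number above each peak is the authors' fold enrichment. Only the control 1 and Bmal1 CKO 2 lists hold peaks at these genes, and both have a summit near the upper end of Dio2, with folds of 6.77 and 3.34.

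Of 15 genes that make, carry or sense thyroid hormone, 11 had an end peak in control 1 and 7 in Bmal1 CKO 2, and 7 had one in both. The highest fold of this list was at Dio2, which encodes a deiodinase that makes active thyroid hormone (chromosome 12, 90724552 to 90739038). Control 1 had a summit at 90738054 inside the gene, 984 bp from its upper end, with a fold of 6.77 from 33 stacked fragments over a background of 4.02. Bmal1 CKO 2 had a summit at 90738084 with a fold of 3.34, from 26 stacked fragments over a background of 7.08. Within each library's own end peaks these folds stood at percentile 97.6 and 69.1. Folds and percentiles of lists that differ in depth and length cannot show whether binding changed. With 1 library per genotype listing the peak, the difference has no replicate check. The 2 other libraries of each genotype listed no peak within 10 kb of Dio2. Dio3, which encodes the deiodinase that inactivates the hormone, had a fold of 2.25 in control 1 and no peak within 10 kb in Bmal1 CKO 2. The transporter gene Slc16a10 had an end peak in both libraries, with folds of 5.78 and 3.60. Thrb, the receptor gene needed for the M opsin of cones, had folds of 3.70 and 3.39, and the cone-enriched receptor gene Rxrg had 3.47 and 2.82. Klf9, a thyroid hormone response gene, had 2.87 and 2.25, and Rxrb had 2.21 and 1.99. Dio1, Crym and Rxra had an end peak only in the control 1 list, with folds of 3.44, 3.22 and 2.23. Among all protein-coding genes, too, more had an end peak only in control 1 than only in Bmal1 CKO 2. Thra, Slco1c1, Ttr and Hr had none at an end in either list. The list did not pass the test in either library (Fisher's exact test, one-sided, p = 0.499 and 0.889).

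Of 16 cone photoreceptor genes, 8 had an end peak in control 1 and 7 in Bmal1 CKO 2, and 5 had one in both. Neither library had an end peak at Opn1sw, the gene of the short-wavelength opsin. Opn1mw, the gene of the middle-wavelength opsin (chromosome X, 74127466 to 74150756), had one in Bmal1 CKO 2 alone, with a fold of 2.78 at 106 bp outside its lower end. The genes Arr3, Gngt2, Pde6h, Cngb3 and Kcne2 had none in either. Gnb3 had folds of 2.65 and 1.97, Sall3 had 4.02 and 2.46, and Guca1a had 2.73 and 2.22 in control 1 and Bmal1 CKO 2. The phosphodiesterase gene Pde6c had 4.26, the transducin gene Gnat2 had 3.44 and the channel gene Cnga3 had 2.61 in the control 1 list, with no end peak in Bmal1 CKO 2. Grk1 had 2.12 in the Bmal1 CKO 2 list alone. Cnga3 was the only gene of the clock, thyroid hormone and cone lists with any peak in a short list. Its peak lay inside the gene near 37233037 on chromosome 1 and was listed in Bmal1 CKO 1 (fold 4.56) and Bmal1 CKO 3 (fold 6.25), as well as in the long lists of control 1 (6.49) and Bmal1 CKO 2 (4.96). The cone list did not pass the test (Fisher's exact test, one-sided, p = 0.972 and 0.930).

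Markers of other retinal cells did not pass the test in any library. In control 1 and Bmal1 CKO 2, end peaks were found at 12 and 9 of 20 rod genes, 11 and 8 of 15 bipolar genes, 12 and 8 of 15 Müller glia genes, 11 and 3 of 15 amacrine and horizontal cell genes, and 12 and 9 of 15 ganglion cell genes. They were found at 6 and 5 of 13 genes of the pigment epithelium and at 7 and 3 of 15 genes of microglia and vessels. Of 20 genes used in nearly all cells 15 and 17 had one. Over all 72 tests of 12 lists in 6 libraries, 0 passed at an adjusted p under 0.05 and 2 had an unadjusted p under 0.05 (Fisher's exact test, one-sided). The lower of them was for the ubiquitously used genes in Bmal1 CKO 2 (17 of 20 genes), with an exact p of 0.0124 and an adjusted p of 0.749. In control 1, 69.5% of all protein-coding genes had an end peak. Gene lists with fewer than 20 genes therefore had little room to pass there after adjustment, even with a peak at every member. The simulated lists had 20 genes and were judged at an unadjusted p. Failing the adjusted limit in control 1 thus does not exclude enrichment of these gene lists. Between genotypes, no list reached an exact permutation p under 0.50, and all adjusted p were 1. Every list but that of the ubiquitously used genes had a share of 0 in all 4 short lists. For such lists the permutation p is the same whatever shares the 2 long lists hold, so it cannot show whether genotype matters.

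**Figure D3:**
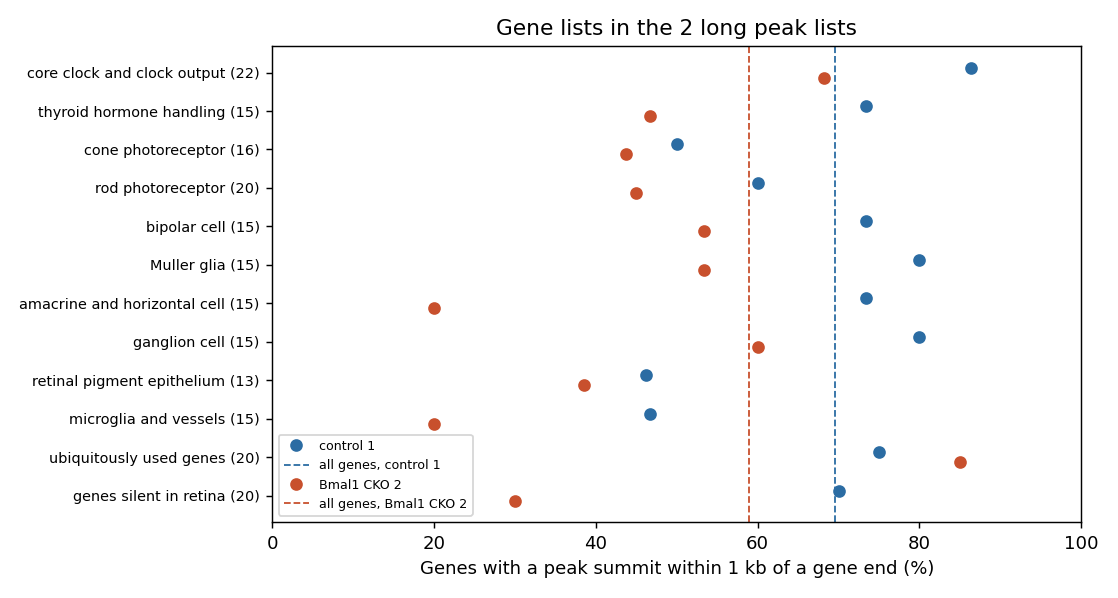
Percent of each gene list (number of genes in brackets) with a peak summit within 1 kb of a gene end in control 1 (blue) and Bmal1 CKO 2 (orange); dashed lines give the share over all 21900 protein-coding genes, 69.5% and 58.9%. Of the core clock genes 19 and 15 of 22 have one and of the cone genes 8 and 7 of 16, and neither list passes the test.

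Overlap between lists did not separate the genotypes. Of the 1444 peaks of Bmal1 CKO 1, 1153 (79.8%) overlapped control 1 and 1275 (88.3%) overlapped Bmal1 CKO 2, where shifted positions gave 4.37% and 3.69%. The 2 long lists shared 74798 of the 138254 peaks of Bmal1 CKO 2 (54.1%, against 4.53% from shifted positions). Control 2 and control 3 shared 279 of 372 peaks (75.0%), and control 3 and Bmal1 CKO 3 shared 280 of 372 (75.3%). Pairs of one genotype overlapped by 87.5% on average (6 pairs, range 75.0% to 97.6%) and pairs across genotypes by 83.6% (9 pairs, 54.1% to 97.1%), a difference of 3.89 percentage points with an exact permutation p of 0.80. With the 372 strongest peaks of each library the means were 56.5% and 63.1%, a difference of −6.51 (exact permutation p = 0.30). Without control 1 the difference was −2.97, and it ranged from 0.656 to 8.40 without the other libraries. The lowest pair across genotypes, at 54.1%, was that of the 2 long lists. By the bases shared by 2 lists over the bases covered by either (Jaccard index), the difference within minus between genotypes was −0.0598.

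Merging gave 241559 regions, of which 169789 were called in 1 library, 70530 in 2 and 230 in all 6. Of the regions called in 2 libraries, 70375 were called in control 1 and Bmal1 CKO 2. No region was called in all 3 controls and no CKO library, and none in all 3 CKO libraries and no control. Each genotype has 1 long list, and a region in it cannot count as specific to the other genotype. Of the peaks of control 2, 96.8% overlapped Bmal1 CKO 2, and of those of Bmal1 CKO 3, 97.1% overlapped control 1. Low counts therefore depend largely on 1 library per genotype and do not show that the genotypes are alike. In at least 2 controls and no CKO library, 4 regions were called. They lay within Psma8 (chromosome 18, 14738832 to 14739042; folds 5.38 in control 1 and 8.02 in control 2), Zfp949 (chromosome 9, 88553086 to 88553441; 4.39 in control 1 and 7.41 in control 3) and Galntl6 (chromosome 8, 58298195 to 58298419; 5.38 in control 1 and 6.21 in control 2), and 16060 bp from Kcnj6 (chromosome 16, 94728593 to 94728920; 3.07 in control 1 and 8.25 in control 3). This count was 31 without Bmal1 CKO 2, 9 without Bmal1 CKO 3, 2 without control 2 or control 3, and 0 without control 1. None of the genes named at these regions is in the clock, thyroid hormone or cone lists. Those lists hold only 22, 15 and 16 of 21900 protein-coding genes, so their absence from 4 regions says little.

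In at least 2 CKO libraries and no control, 120 regions were called, 117 of them in Bmal1 CKO 1 and Bmal1 CKO 2. The region with the highest mean fold lay 1553 bp from the vomeronasal receptor gene Vmn2r102 (chromosome 17, 19658477 to 19658846; 9.69 in Bmal1 CKO 1 and 4.10 in Bmal1 CKO 2). Others among the top 10 lay in Gm7697, Gm2977, Gm51421, Gm9495 and Gm17660, in Zfp993, and near Gm16513, Gm11239 and Gm16405, with mean folds of 5.37 to 5.84. By chromosome, 25 of the 120 lay on chromosome 5, 20 on chromosome 8 and 15 on X. The count was 911 without control 1, 3 without Bmal1 CKO 1 and 0 without Bmal1 CKO 2. Control-only and CKO-only regions numbered 8 and 10 with the same number of peaks per library, and 18 and 25 at a fold of at least 5. They numbered 2 and 99 at a −log10 q-value of at least 5, and 1 and 93 without the 2 long lists.

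**Figure D4:**
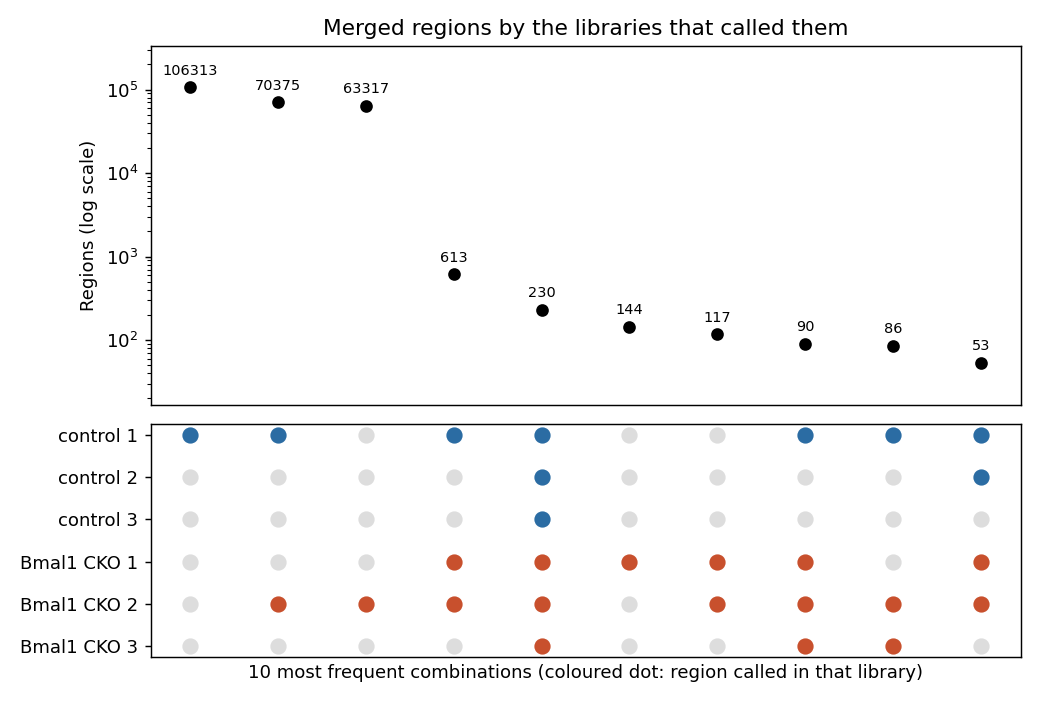
Number of merged regions (logarithmic axis) for the 10 most frequent combinations of libraries; a coloured dot below marks a library that called the region (blue control, orange Bmal1 CKO). The combination of control 1 and Bmal1 CKO 2 holds 70375 regions and that of all 6 libraries 230, and no combination of controls alone with 2 or more libraries is among the 10.

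The strongest peaks of every library lay at places called in both genotypes. The 5 peaks with the highest −log10 q-value of each library all lay in regions called in all 6 libraries, and of the first 100 per library 82 to 99 did. A region on chromosome 9 (35305070 to 35305719, within the non-coding gene Gm33838) had folds of 19.6, 24.7 and 24.6 in controls 1 to 3 and 20.1, 15.7 and 24.7 in Bmal1 CKO 1 to 3. A region within Aida on chromosome 1 (183299012 to 183299691) had folds between 15.9 and 21.9 over the 6 libraries, and one within Zc3h7a on chromosome 16 (11143912 to 11144459) between 15.6 and 27.0. Others lay within Chl1 (lowest fold 16.9), Kctd16 (16.6) and Cldn34d (16.1), in gene deserts 391565 bp from Nbea (16.7) and 372421 bp from Csmd1 (16.3), 64541 bp from Cr2 (17.0) and 63474 bp from Fam171a1 (16.8). None of the clock, thyroid hormone or cone genes is among these genes. Those lists hold only 22, 15 and 16 of 21900 protein-coding genes, so their absence from so few regions says little. Of the 230 regions, 6 (2.61%, 95% Clopper-Pearson interval 0.963% to 5.59%) had their summit at a gene end, where uniform placement gives 3.12%. These regions made up 60.5%, 66.9% and 47.4% of the peaks of control 2, control 3 and Bmal1 CKO 3, 17.5% of Bmal1 CKO 1, and 0.133% and 0.171% of the 2 long lists.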

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

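Settings that leave out the 2 long lists, and the use of gene ends and gene bodies, were chosen after seeing the data. No genotype comparison could pass a threshold, so only directions and counts can change. Requiring a fold of at least 5 turned the difference in log10 peak number to −0.154, that in gene-end share to −0.785 percentage points and that in overlap to −3.38, and gave 18 control-only and 25 CKO-only regions. With the same number of peaks per library the gene-end difference was −0.627 and the overlap difference −6.51, with 8 control-only and 10 CKO-only regions. A −log10 q-value of at least 5 left 2 control-only regions, with a log10 peak difference of 0.0820 and a gene-end difference of 2.66. A 5 kb window gave a gene-end difference of 2.51. Without the 2 long lists the overlap difference was −6.78 and 1 control-only region was found. Leaving out each library in turn gave a log10 peak difference between −0.542 and 1.08, a gene-end difference between −0.875 and 3.62, an overlap difference between −2.97 and 8.40, 0 to 31 control-only regions and 0 to 911 CKO-only regions. The cause was not tested for these changes, apart from the fewer peaks or libraries that each setting leaves. The count of enriched gene lists (Fisher's exact test, adjusted) was 0 as reported, with 2 at an unadjusted p under 0.05, and 0 in all 13 alternatives. The smaller gene lists had little room to pass in control 1 as reported, so this count does not exclude enrichment there. The remaining alternatives, chromosomes 1 to 19 and X alone, a 5 kb window, one peak per interval and a larger minimum overlap, kept every direction and moved no count by over 1.5 times. Labels share replicate numbers between genotypes, but deviations of same-numbered libraries over 71540 regions correlated at −0.464, −0.328 and −0.132. Of these regions 70375 were called in control 1 and Bmal1 CKO 2 alone, so list length sets these values and they do not show whether the numbers pair the samples. With the replicate block the log10 peak difference (0.193), the gene-end difference (1.25) and the overlap difference (3.89) had a p of 0.75 each by exact sign flips, where the smallest possible is 0.25. Region counts come from no test and have no blocked form. The E-box count was not run, for want of a genome sequence here. Depth was lowest in control 2, control 3 and Bmal1 CKO 3, at 0.560 to 0.852 fragments per base. Scaled to them, 0 of the clock, thyroid hormone and cone end peaks of either long list reached those lists' lowest −log10 p-value, but that limit (5.05 to 6.76, against 2.76 and 2.87 in the long lists) is itself a property of the lists, so how far depth alone explains a missing peak is open.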

Other observations

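Of the tests below, those on depth, on the threshold, on genotype, on binding at promoters, on splits of the libraries, on gene families and on dense intervals were chosen only after the result was seen. Gene families grouped by symbol differed widely in both long lists. End peaks were found at 38 of 40 proteasome genes in control 1 and 39 in Bmal1 CKO 2, at 73 and 69 of 78 mitochondrial ribosomal protein genes, at 75 and 74 of 83 cytosolic ribosomal protein genes and at 338 and 321 of 397 Zfp zinc finger genes. Chemosensory receptor families had few, with 217 and 201 of 1110 olfactory receptor genes, 7 and 13 of 231 Vmn1r genes, 12 and 21 of 124 Vmn2r genes and 1 and 3 of 35 bitter taste receptor genes. All of these families differed from the other protein-coding genes in both libraries (Fisher's exact test, two-sided, largest adjusted p = 0.000149 over 26 tests), with genes of a family not being independent. By the same exact test, keratin genes had end peaks at 38 of 53 members in control 1 (71.7% against 69.5% of other genes, adjusted p = 0.881) and at 20 in Bmal1 CKO 2 (37.7% against 59.0%, adjusted p = 0.00248). Potassium channel genes had them at 63 and 39 of 93 members (exact test, adjusted p = 0.764 and 0.00131), and the difference between the libraries was not tested for either family.

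Bmal1 CKO 1 had 383 of its 1444 peaks (26.5%) in the 5 intervals of 2 Mb where its own peaks were densest. These were chromosome 8 from 20000001 to 22000000, with 110 peaks among 28 Defa and 10 Defb defensin genes, chromosome 5 from 94000001 to 96000000, with 80 peaks among 14 Pramel genes, chromosome 4 from 146000001 to 148000000, with 77 peaks among 14 Zfp genes, chromosome 1 from 84000001 to 86000000, with 65 peaks, and chromosome 5 from 14000001 to 16000000, with 51 peaks. The same intervals held 8.78% of the peaks of control 2, 7.80% of control 3 and 9.25% of Bmal1 CKO 3, and 0.775% and 1.19% of control 1 and Bmal1 CKO 2. Since the intervals were picked by the peaks of Bmal1 CKO 1, its higher share cannot be read as a difference between libraries. Peaks were sparser on X than on autosomes in the long lists, at 26.1 against 72.8 per Mb in control 1 and 18.9 against 56.2 per Mb in Bmal1 CKO 2 (ratios of 0.358 and 0.336). In the short lists the ratio of X to autosomes was 0.987 in control 2, 0.837 in control 3, 1.44 in Bmal1 CKO 1 and 0.738 in Bmal1 CKO 3.

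The first pattern is that 2 lists were far longer than the other 4. Genotype alone is argued against, since both genotypes (2 of 2) had a long and a short list. With 3 libraries per genotype a short list in each was certain, so only the place of the long lists bears on this. That place rests on the series record, which the lists cannot check. Depth is argued against for Bmal1 CKO 1, whose list was 124 times shorter than that of control 1 at a background only 1.24 times lower. A laxer p-value or q-value limit is argued against, since the shorter long list was still 28.6 times as long as the longest short one at a −log10 q-value of at least 5 and 40.3 times at a −log10 p-value of at least 6.76, but at a fold of at least 5 it was 3.16 times as long. For control 2, control 3 and Bmal1 CKO 3 depth cannot be told apart from other causes, because the long-list libraries were at least 4.06 times deeper and no library of like depth had a long list. Differences in immunoprecipitation or library quality stay open and were not tested.

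The second pattern is the set of 230 regions called in all 6 libraries, which hold the strongest peaks of each list. Binding at promoters of protein-coding genes is argued against for most of them, since 6 of 230 (2.61%, upper bound 5.59%) had their summit at a gene end. Their share at gene ends was 0.837 times that from uniform placement, with an upper bound of 1.79 times. That ratio counts both ends of a gene, so it cannot exclude an excess at promoter ends alone. Ends of non-coding genes were not counted. A candidate explanation is reads piling up at multi-copy or collapsed sequence whatever the antibody binds. The local background around these peaks was 1.38 to 2.21 times that around the other peaks of the same library, but it appears to count the peak's own fragments, so stronger peaks raise it whatever their cause, the values decide nothing and this explanation stays open. BMAL1 binding in cells that kept the gene also stays open, since the labels do not say which cells lost it and no motif was counted.

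For the third pattern, the peaks at gene ends in the 2 long lists, a candidate explanation is chromatin open in most cells, or a base-composition bias of promoters, in place of BMAL1 targets. It predicted that ubiquitously used genes have end peaks at least as often as clock genes and more often than silent genes in both libraries. Clock and ubiquitously used genes had them at 19 of 22 and 15 of 20 genes in control 1 and at 15 of 22 and 17 of 20 in Bmal1 CKO 2 (Fisher's exact test, two-sided, p = 0.445 and 0.284). Silent genes had them at 14 of 20 and 6 of 20 (exact test against ubiquitously used genes, p = 1 and 0.00106, the latter 0.00639 adjusted over 6 tests). Clock genes were above ubiquitously used genes in control 1, without passing a test, and the families above, chosen after the values were seen and not tested against clock genes, had high shares for proteasome and ribosomal proteins and low ones for olfactory receptors in both libraries, so neither explanation is excluded.

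Chance as the source of genotype-specific regions was examined over the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. All 10 splits, the real one included, gave on either side at least as many one-sided regions as the 4 control-only regions. On either side, 7 gave at least as many as the 120 CKO-only regions. The real split reached 4 by its 120 CKO-only regions as well. The highest other split gave 71116, and it put control 1, Bmal1 CKO 1 and Bmal1 CKO 2 together. All 4 splits that placed the 2 long lists on one side gave between 70382 and 71116, which follows from the 70375 regions called in those 2 lists alone and restates their length, a structure of the samples other than genotype. These 4 are among the 7 splits that reached 120. The rest of the 7, the real one included, gave 120, 133 and 120. Each had Bmal1 CKO 1 and Bmal1 CKO 2 on one side and control 1 on the other.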
